A study of Caenorhabditis elegans with 165 samples.

How the data were processed

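The series holds 165 samples, of which 12 are RNA-seq libraries with a file of their own: 4 of the wild-type strain N2, 4 of strain 15eh1 (X-V) and 4 of strain YPT41 (X-II). The library titles name larvae from L1 to L3, while the design text of the series names L3, and the protocols in the labels describe ChIP from embryos, so the stage of each library is not given more closely. The other 153 samples are ChIP-seq and input samples without files here, 3 of them without a group, and are not analysed here. Read counts per gene were deposited as 1 table per library; their unit, whole counts, was read from the values and from the summary lines at the end of each file. Per the submitters' processing notes, CASAVA 1.8, Bowtie 1.2.0, MACS 1.4.3, bedtools, TopHat2 2.1.1, SAMtools 1.6 and HTSeq were used, with no role or order given. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Antisense and overlapping transcripts, and reads shared between similar genes, therefore cannot be told apart in these counts.

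Summary lines stayed out of all library sizes. Reads without a feature made up 2.48% to 4.25% of each library, ambiguous reads 0.656% to 0.893% and reads without a unique position 13.2% to 22.7%. Total gene counts ranged from 8237095 to 31234047, and 15296 to 18132 genes had a count. A floor of 3 counts corresponds to 0.0960 to 0.364 CPM in a single library. Of 20389 gene identifiers, 19879 matched a locus tag of the RefSeq gene table for the WBcel235 assembly, and 510 did not. That table was used for symbols, chromosomes and gene order only. Of the 13186 tested genes, 12983 had a place in it. Libraries of a strain were checked for repeated content, and none repeated another (lowest chi-square per gene 22.3).

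Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter by group, and quasi-likelihood tests in 1 fit of all 12 libraries with the strain as the only term. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons were: X-V against N2, X-II against N2, and X-V against X-II. Log2 CPM values use a prior count of 2. For each chromosome end, the 100 tested genes nearest the end formed a window, and 13 regions (12 ends and all of X) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes. Camera with an estimated correlation and the rotation test fry stand beside it. The mean log2 CPM of each window relative to the other autosomal genes was compared between libraries by exact two-sided permutation tests, for which 4 against 4 libraries give at best p = 0.0286. Runs of neighbouring genes without reads were sought among genes with at least 10 counts per library in N2, at most 10 annotated genes apart, with a mean under 0.1 of the N2 mean and at most 3 counts per library in a fusion strain. Ratios of pooled counts carry 95% intervals, and these and the floors cover counting error only.

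Gene lists were fixed before the data were examined, as were the tests, the windows, the rule for naming genes and the first set of alternatives. The 26 lists cover dosage compensation, proteins targeted by ChIP in the series, sex determination, histone methyltransferases and demethylases, telomere maintenance with the DNA damage checkpoint, cuticle collagens, the molting cycle, the heterochronic pathway, the germline, spermatogenesis, vitellogenins, embryonic regulators, ribosomal proteins, histones, mitochondrially encoded genes, innate immune effectors, the intracellular pathogen response, heat shock with the unfolded protein response, detoxification, fatty acid metabolism, insulin and stress resistance, muscle, intestine, neurons, epidermis with seam, and the F-box and MATH families. Lists with fewer than 3 tested members had no test.

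Genes were named by a rule, and any beyond it were added after their values were seen. Genes under the rule are as follows. For each comparison with N2 they are the 6 with the largest rise and the 6 with the largest fall among genes past the threshold, if all 4 libraries of one strain lie above all 4 of the other, the higher mean is at least 1 CPM, and the gene has a name. To these come the 2 with the smallest adjusted p in each list with at least 3 members past the threshold, and the 4 with the smallest adjusted p in each window of the fused autosome. In X-V against X-II it is 4 in each direction. Genes of the dosage compensation list are covered in every comparison.

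Each library's deviation from its strain mean was correlated between strains to see whether replicate numbers pair the libraries. The 12 correlations of libraries with the same number ranged from 0.319 to 0.942, all above the limit of 0.1 set for pairing, and 6 of the 12 were the best match of their library. Among replicates 2 to 4 alone they ranged from −0.12 to 0.44, with 4 of 9 above 0.1, so the pairing rests largely on replicate 1. Nothing in the labels says that libraries came from separate cultures, and p-values therefore measure only the spread between these samples.

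Simulated counts were drawn with the replicate effects and the spread of the fit with the block, which favours that fit. On simulated counts for X-V against N2 (12977 genes), the fit without a block recovered 0 of 98 genes changed 2-fold and 11 of 100 changed 4-fold, with 0 false calls. The fit with a block recovered 16 and 85, with 4 false calls. For X-II against N2 (12993 genes) the numbers were 0 of 100 and 8 of 97 without a block, with 0 false calls, and 24 and 86 with a block, with 8 false calls. Windows shifted by −0.50 were recovered at −0.54 for the V right end and −0.53 for the II left end, with 0 of 12 other regions called. Apart from the shared replicate effects, genes were drawn independently. In X-V against N2 the estimated correlation between genes was 0.0593 for the V right window and 0.131 for X. The 0 of 12 therefore cannot show how often camera calls a region whose genes vary together.

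The alternatives were DESeq2 1.42.0, RLE and upper quartile scaling, scaling on autosomal genes outside the windows, 2 other filters, glmTreat against a fold of 1.5, fits of the 2 compared groups alone, windows of 50 and 200 genes, X without its ends, the replicate block, and leaving out each library. Added after the data were seen were replicates 2 to 4 alone, the block joined with an estimated correlation, the II left window without its 7 leftmost genes, other limits for runs without reads, the settings for the other chromosome ends, and the naming rule applied to the blocked fit.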

Results

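Transcripts of Caenorhabditis elegans larvae were counted by RNA-seq in 3 strains, with 4 libraries per strain. N2 is the wild-type laboratory strain. In the strain called X-V here, the X chromosome is joined to chromosome V, and in the strain called X-II it is joined to chromosome II (X;V and X;II in the figures). Hermaphrodites lower the expression of both X chromosomes through the dosage compensation complex, a condensin-related complex that the series profiled by ChIP-seq. The fusions place autosomal genes next to X, so the comparisons ask whether expression changes on the autosome joined to X, near the junction in particular. The labels do not name the joined ends, and both ends of V and of II were therefore measured in the same way as every other chromosome end. Gene counts per library were 13539912, 12349109, 16757544 and 31234047 for N2 replicates 1 to 4. They were 12153883, 13274717, 21910442 and 27079687 for X-V, and 10980737, 16684543, 8237095 and 20573267 for X-II. After a filter on low counts, 13186 genes were tested.

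Replicate 1 of each strain carried adult and germline transcripts that were rare in the other 9 libraries. Vitellogenins, the yolk proteins made in the intestine of adult hermaphrodites, took 12.2% of the counts of N2 replicate 1, 12.58% of X-V replicate 1 and 6.81% of X-II replicate 1. In replicates 2 to 4 they took between 0.000294% and 0.0449%. All 43 tested germline genes were higher by more than 1 on the log2 scale in replicate 1 of each strain, with medians of 4.84 in N2, 4.88 in X-V and 4.00 in X-II. Replicate 1 lay apart from replicates 2 to 4 on the first principal component, which held 64.2% of the variance. X-II replicates 3 and 4 lay apart on the second, with 12.32% of the variance, at −46.10 and −93.46. The spread between libraries of a strain was therefore wide, with a biological coefficient of variation of 0.638. It was 0.297 when the replicate number was kept as a block. Pairing by replicate number passed the limit set for it, but rests largely on replicate 1, as given with the processing.

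**Figure D1:**
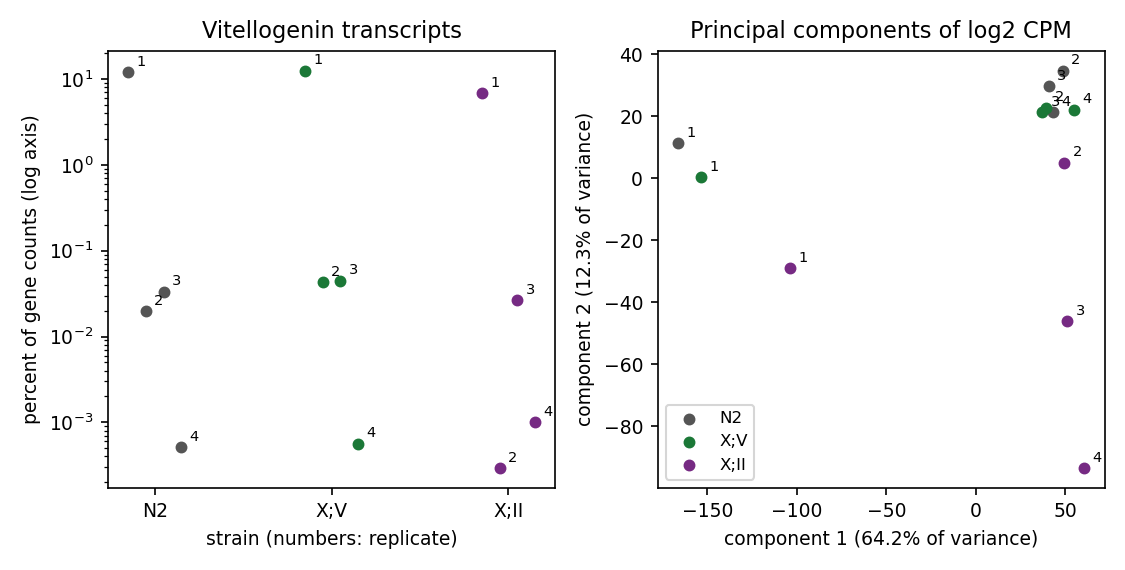
Left, percent of gene counts from vitellogenin transcripts in each of the 12 libraries, on a log axis, with the replicate number beside each point. Right, the first 2 principal components of log2 CPM (64.2% and 12.32% of the variance). Replicate 1 of each strain held 6.81% to 12.58% vitellogenin counts and lay apart from the other libraries on the first component.

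Genes at the right end of chromosome V were expressed at lower levels in X-V than in N2. The 100 tested genes nearest that end fell to a median of 0.698 of the N2 level, a median log2 fold change of −0.52 with quartiles of −0.76 and −0.23, and 88 of the 100 lay below 0. Among the highly expressed genes of this window, mlt-11, which acts in molting, was counted at 518 ± 129 CPM in X-V and 1175 ± 296 in N2 (SD, n = 4). The hypoxia-response transcription factor hif-1 stood at 373 ± 82.6 against 527 ± 78.7 CPM, and rpl-8, a protein of the large ribosomal subunit, at 1472 ± 301 against 1756 ± 283 CPM. With dct-16, at 234 ± 137 against 662 ± 330 CPM, these are the 4 named genes of the window with the highest N2 level. They were chosen after the values were seen, and none of them passed the test for single genes. The left end of V did not share this difference, with a median of 0.05, and neither did X as a whole, with a median of 0.04 over 1998 genes.

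The shift of the V right window was tested with limma's camera over 13 regions (adjusted p = 2.97e-32, and adjusted p = 0.00144 with an estimated correlation). Relative to the other autosomal genes, the mean log2 CPM of the window was lower by 0.56 in X-V on average over the 4 replicate pairs (−0.56 ± 0.11, SD of the paired differences), and lower in 4 of 4 pairs. An exact two-sided permutation test of the 8 library values that ignores the pairs gave p = 0.0857 (adjusted p = 1 over 13 regions), and 0.0286 is the smallest p that 4 against 4 libraries allow. In bins of 50 tested genes counted inward from the V right end, the medians were −0.55, −0.43, −0.46 and −0.34 for the first 4 bins, and 0.00 and 0.05 for the last 2 of the 12. The camera adjusted p was 0.819 for the left end of V and 0.819 for X. Without X-V replicate 1, X genes had a median of 0.12 and a camera adjusted p of 0.00420. That fit kept N2 replicate 1, in which X was low (−0.71 relative to the other autosomal genes, −0.68 in X-V replicate 1). In replicates 2 to 4 alone X did not pass. The 10 ends of the other chromosomes had medians from −0.02 to 0.09, and 0 of them passed camera, with 0 at an unadjusted p under 0.05 and 0 by limma's fry.

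**Figure D2:**
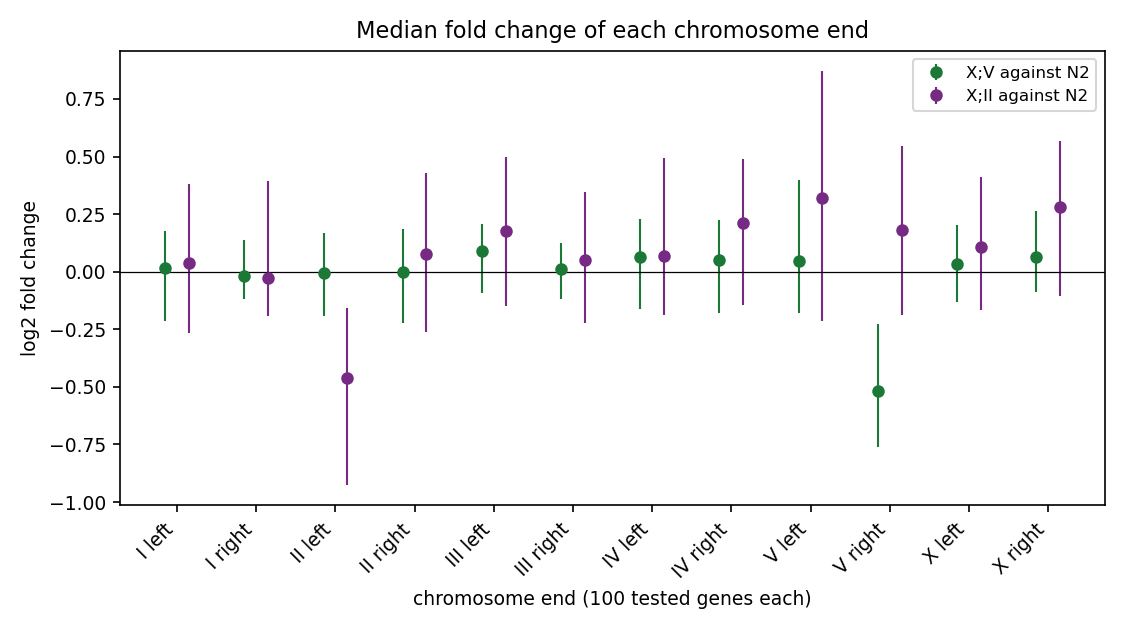
Median log2 fold change against N2 of the 100 tested genes nearest each of the 12 chromosome ends, with vertical lines over the quartiles over genes. The V right end in X-V (−0.52) and the II left end in X-II (−0.46) lie below every other end.

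No single gene passed edgeR's quasi-likelihood test in X-V against N2. The count was 0 of 13186 at a Benjamini-Hochberg adjusted p under 0.05, with 206 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.187, while DESeq2 called 18 genes, 9 higher and 9 lower. With the replicate block, edgeR called 9 genes, but only srw-85 in replicates 2 to 4 with the block (adjusted p = 0.0102), where fewer libraries also leave less power. A simulation with set changes held 4 false calls with the block. In 20 simulations of unchanged groups, the block gave at most 3 calls for X-V against N2. Lower in X-V were srw-85, a chemoreceptor-family gene (log2 fold change −4.17 ± 0.37, SE), bgnt-1.3 (−3.09 ± 0.41) and herc-1, a homolog of HERC ubiquitin ligases (−1.79 ± 0.18). Higher were pgp-8, an ABC transporter of the P-glycoprotein family (3.53 ± 0.39), the glutathione S-transferase gst-24 (2.81 ± 0.36), the ZIP-family zinc transporter zipt-2.3 (3.48 ± 0.46), the bZIP factor zip-11 (1.96 ± 0.22), F44E7.5 and Y39G8B.7. Each moved in the same direction in 4 of 4 pairs, and their edgeR adjusted p with the block lay between 0.00247 and 0.0209. These 9 were named after their values were seen. Without N2 replicate 1, the fit without a block called 1 gene. None of the 10 genes of the dosage compensation complex was called: dpy-21 had the lowest p among them (log2 fold change −0.43 ± 0.22, SE; 111.8 ± 23.6 against 151 ± 16.6 CPM, SD), and their median log2 fold change was −0.08.

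Molting-cycle genes, the proteases and matrix proteins of the larval molts, were lower as a group in X-V. Their median log2 fold change was −0.34 and 8 of 69 lay above 0 (camera adjusted p = 1.12e-10; adjusted p = 0.984 with an estimated correlation). Ribosomal protein genes were higher as a group, with a median of 0.20 and 65 of 74 above 0 (camera adjusted p = 0.00103; adjusted p = 0.984 with an estimated correlation). Genes of synaptic and neuropeptide proteins had a median of 0.29 with 44 of 49 above 0 (camera adjusted p = 2.35e-05; adjusted p = 0.984 with an estimated correlation). In each of the 3 lists 0 members were called over all genes and 0 adjusted over the list alone, by edgeR. Replicate 1 differed from replicates 2 to 4 in all 3 lists: in N2 its median difference was −0.85 for molting genes, −0.85 for ribosomal proteins and −1.46 for neuronal genes. Without N2 replicate 1 the camera adjusted p was 0.909 for both ribosomal and neuronal genes, with medians of 0.03 and 0.08. That fit kept X-V replicate 1, which was low in the same 2 lists, with median differences of −1.02 and −1.30. In replicates 2 to 4 alone both calls were kept. The ribosomal call was also lost without X-V replicate 2 (0.11, adjusted p = 0.292) and without X-V replicate 3 (0.05, adjusted p = 0.755).

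In X-II, the 7 leftmost genes of chromosome II had almost no reads. The cuticle collagen sqt-2 had 11 counts over the 4 X-II libraries and 8347 over the 4 N2 libraries, a ratio of pooled CPM of 533 (95% counting interval 298 to 1069). The transcription factor homolog gmeb-1 had 5 against 3266 counts, a 459-fold difference (197 to 1415), and best-3, a bestrophin channel homolog, 2 against 687 counts, a 241-fold difference (66.6 to 1998). Its neighbour best-4 had 0 counts in X-II and was at least 53.9-fold lower, taking 3 counts over the group as the floor. The remaining 3 were osta-1 with 1 count, 2L52.1 with 5 and enee-1 with 4, against 99, 298 and 197 in N2. In X-V these 7 genes kept 127 to 6379 counts. Reads returned at the 8th gene, F23F1.4, which stood at 9.15 ± 5.35 CPM in X-II and 22.01 ± 8.45 in N2 (SD, n = 4).

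**Figure D3:**
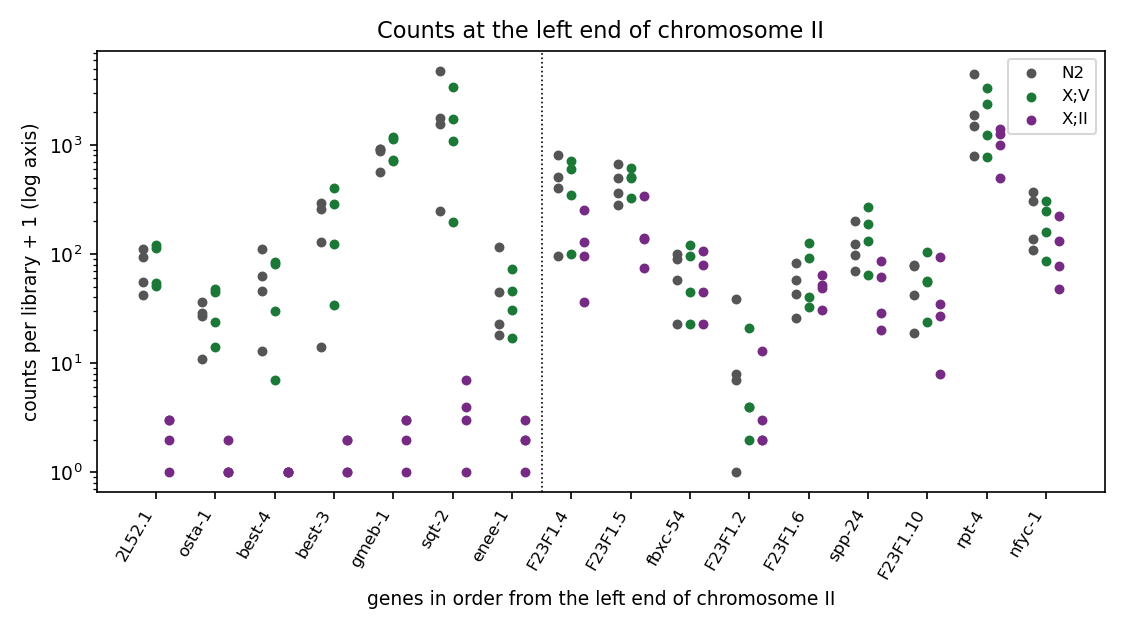
Counts per library, plus 1, on a log axis for the first 16 annotated genes of chromosome II in order from its left end, for 4 libraries of each strain. Left of the dotted line are the 7 genes with at most 11 counts over all X-II libraries.

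Beyond these genes, the left end of II was expressed at lower levels in X-II than in N2. The 100 tested genes nearest the end had a median log2 fold change of −0.46, a fold of 0.725, with quartiles of −0.92 and −0.16, and 80 of them lay below 0 (camera adjusted p = 9.08e-19; adjusted p = 0.00254 with an estimated correlation). Over the next 100 tested genes inward from the 7 leftmost, the median was −0.44 (camera adjusted p = 6.72e-09). The molting gene mlt-10 stood at 158 ± 52.06 CPM in X-II and 419 ± 49.9 in N2, and sptl-1, a subunit of serine palmitoyltransferase, at 47.9 ± 1.10 against 106 ± 28.4 CPM (SD, n = 4). Both were lower in 4 of 4 pairs and passed edgeR with the replicate block only (adjusted p = 0.0122 and 0.0109). They are 2 of the 6 named genes of this window with the highest N2 level, and were singled out after their values were seen. The other 4 of these, mlt-8, cdc-37, scc-2 and ubxn-3, had log2 fold changes of −0.50, −0.57, −0.66 and −0.50 and did not pass with the block. The mean relative log2 CPM of the whole window differed by −0.81 ± 0.22 (SD of the paired differences, 4 of 4 pairs lower, exact two-sided permutation p = 0.0286, adjusted p = 0.371 over 13 regions). For the 93 genes of the window left without the 7 leftmost, the difference was −0.47 ± 0.22 (4 of 4 pairs lower, exact two-sided permutation p = 0.0571). The size depended on the window: the median was −0.70 over 50 genes and −0.25 over 200, and −0.76 without X-II replicate 1. Under the block with an estimated correlation, the camera adjusted p was 0.0587.

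**Figure D4:**
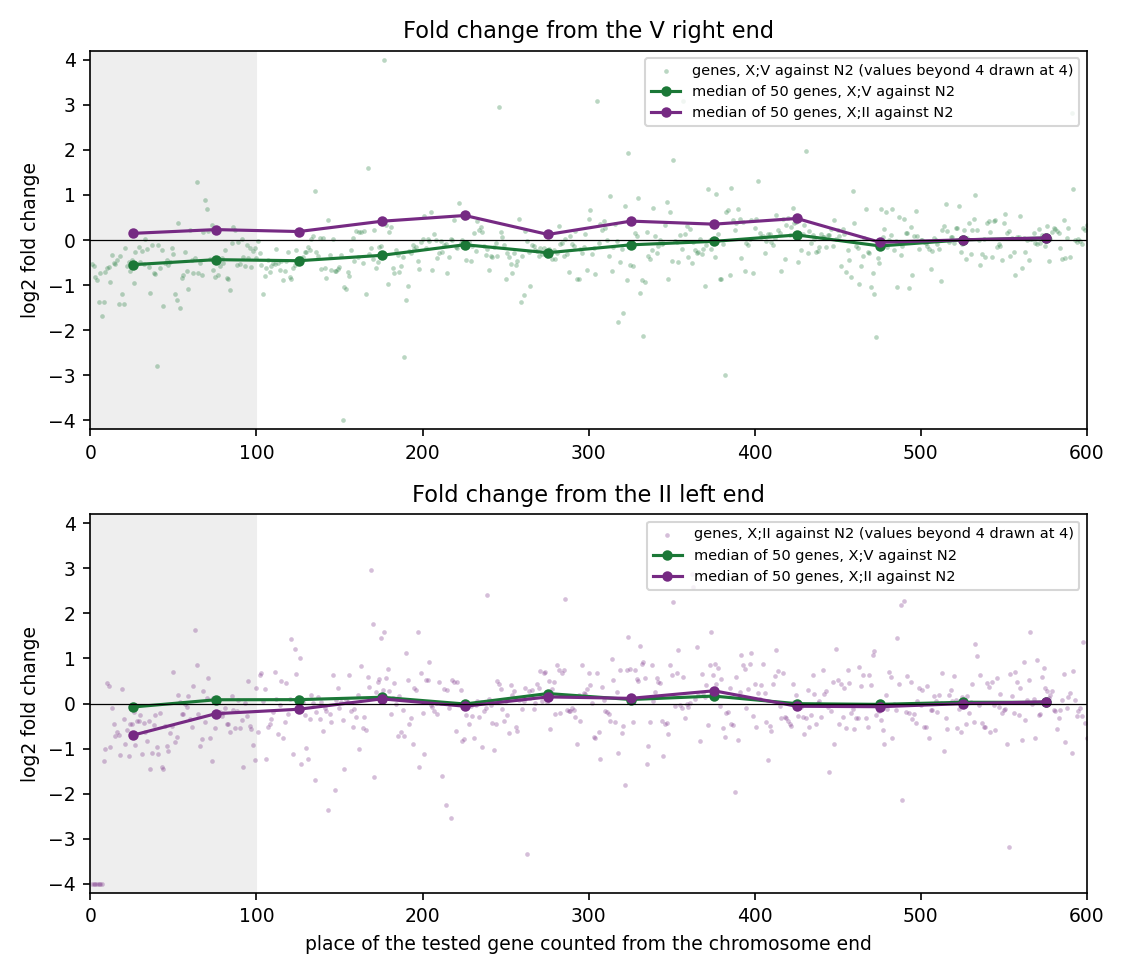
Log2 fold change by gene order, counted inward from the V right end (top) and the II left end (bottom). Dots are single genes of the strain fused to that autosome, lines join medians of 50 tested genes in both strains, and the grey band marks the 100-gene window. The first medians are −0.55 on V in X-V and −0.70 on II in X-II.

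The right end of II and the X chromosome did not differ from N2 by camera in X-II, with medians of 0.08 (adjusted p = 0.833) and 0.16 (adjusted p = 0.249). X passed without X-II replicate 1 (median 0.15, adjusted p = 0.00379). That fit kept N2 replicate 1, in which X was low (−0.71 relative to the other autosomal genes, −0.60 in X-II replicate 1). In replicates 2 to 4 alone X did not pass. Of the 10 other ends 0 passed camera and 0 passed fry, with 2 at an unadjusted p under 0.05: the left end of V at 0.32 and the right end of X at 0.28. Both passed without X-II replicate 1 (adjusted p = 0.0169 and 0.00759), a fit that kept N2 replicate 1, in which both ends were low (−1.53 and −0.49). In replicates 2 to 4 alone neither passed, while with the block added the left end of V did (camera adjusted p = 0.0480). In mean relative log2 CPM, the V left, III left and IV left ends were lower in X-II in 0 of 4 pairs. Their differences were 0.25 ± 0.12, 0.16 ± 0.11 and 0.05 ± 0.07 (SD of the paired differences; exact permutation p = 0.314, 0.457 and 0.686). RLE scaling in edgeR moved the median of all genes by −0.10 in this comparison.

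Across the genome, 29 of 13186 genes differed between X-II and N2 by edgeR's quasi-likelihood test, 21 higher and 8 lower. Antimicrobial peptide genes of the caenacin family rose: cnc-6 by 6.57 ± 0.90 on the log2 scale (SE; 10.3 ± 5.20 against 0.115 ± 0.0789 CPM, SD, n = 4; edgeR adjusted p = 0.014), cnc-2 by 5.39 ± 0.69 (adjusted p = 0.0118) and cnc-4 by 3.17 ± 0.47 (adjusted p = 0.0182). With the C-type lectins clec-7 (1.98 ± 0.29) and clec-82 (3.45 ± 0.56) they made 5 of the 169 tested innate immune effectors that rose. The genes cnc-4, clec-7 and clec-82 were named after their values were seen. Adjusted over the list alone, 16 rose and 3 fell. The list's median was 0.38 with 111 of 169 above 0 (camera adjusted p = 0.00299; adjusted p = 0.828 with an estimated correlation), and its call was lost without N2 replicate 1 (0.17, adjusted p = 0.238) and without X-II replicate 4 (0.04, adjusted p = 0.323). Immune effectors were lower in replicate 1 of each strain, by medians of −0.77, −0.71 and −0.54 in N2, X-V and X-II. The fit without N2 replicate 1 kept X-II replicate 1, and in replicates 2 to 4 alone the call was kept.

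The largest rise belonged to suex-1, with 1172 counts over the X-II libraries and 0 over N2, at least 556-fold higher with the floor of 3 counts over the group. This bound rests mostly on X-II replicate 4, which holds 855 of the counts, and falls to 213-fold without it. Its CPM of 53.5 in X-II replicate 4 lay far above the other 3 X-II libraries. Also among the genes that rose were srlf-34 (6.36 ± 0.64; 132 ± 109 against 1.59 ± 0.435 CPM; edgeR adjusted p = 0.00198), gtnt-25 (4.02 ± 0.56, adjusted p = 0.0142) and bgnt-1.2 (3.93 ± 0.60, adjusted p = 0.0203). Other genes that rose were hmit-1.1 and hmit-1.2, both myo-inositol transporter homologs (3.46 ± 0.59 and 2.68 ± 0.44), the astacin-family protease nas-9 (1.98 ± 0.31) and scl-2 (3.48 ± 0.58). Outside the left end of II, srw-85 fell by 3.79 on the log2 scale (SE 0.63, adjusted p = 0.0346) and herc-1 fell by 1.55 (SE 0.26, adjusted p = 0.035). The hmit-1 genes, nas-9, scl-2 and herc-1 were named after their values were seen. They are not in the tally of fits without 1 library given below. Of the 29 genes, 12 lay on V, 8 on II and 2 on X. None of the 10 genes of the dosage compensation complex was called, and their median was −0.17. In this fit capg-1 had the largest difference (−0.76 ± 0.68, SE), which ran from −1.29 to 0.14 without single libraries. Several named genes belong to families of similar sequence (cnc, hmit-1, best, bgnt and gtnt), and their counts may be shared or lost between copies.

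The count of changed genes depended on the model. With the replicate block 686 genes were called in X-II against N2, 541 higher and 145 lower, all 29 among them, and in replicates 2 to 4 alone 160 with the block and 134 without, against 6 in a fit of the 2 groups alone; DESeq2 called 382, 234 higher and 148 lower. Leaving out single libraries gave 4 genes without N2 replicate 2, 5 without N2 replicate 3, 7 without N2 replicate 4, 16 without X-II replicate 2, 8 without X-II replicate 3 and 9 without X-II replicate 4. The 3 genes gmeb-1, sqt-2 and 2L52.1 and, among those that rose, srlf-34 passed in all 8 fits that leave out 1 library. The gene cnc-2 passed in 6 of the 8, cnc-6 and gtnt-25 in 4, suex-1, best-3, best-4 and osta-1 in 3, bgnt-1.2 in 2 and srw-85 in 1.

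Lists of neuronal, histone and insulin-pathway genes were higher as groups in X-II, without single genes past the test over all genes. Neuronal genes had a median log2 fold change of 0.76 with 45 of 49 above 0 (camera adjusted p = 7.44e-06; 0.791 as the adjusted p with an estimated correlation), and 10 of them rose under the block, among them the FMRFamide-like neuropeptides flp-5 (1.18 ± 0.21, SE) and flp-24 (0.97 ± 0.21). The mean log2 CPM of the list was 3.92, 5.47, 5.30 and 5.00 in N2 replicates 1 to 4 and 4.61, 5.48, 6.00 and 6.25 in X-II, so pair 2 hardly differed and X-II replicates 3 and 4, the libraries apart on the second component, stood highest. Histone genes had a median of 0.83 (camera adjusted p = 1.78e-05; adjusted p = 0.624 with an estimated correlation), with 3 higher adjusted over the list alone and 4 under the block, including the linker histone hil-1 (2.01 ± 0.30). Genes of the insulin pathway and stress resistance had a median of 0.70 (camera adjusted p = 5.85e-04; adjusted p = 0.0669 with an estimated correlation; fry adjusted p = 0.00969). The block called 4 of these 16, among them icl-1, the glyoxylate cycle enzyme, at 9428 ± 3691 against 3300 ± 2211 CPM. Ribosomal proteins had a median of 0.43 with 74 of 74 above 0 (camera adjusted p = 1.89e-05; adjusted p = 0.83 with an estimated correlation). The ribosomal call was lost without N2 replicate 1 (0.17, adjusted p = 0.0647) and without X-II replicate 4 (0.11, adjusted p = 0.118). The fit without N2 replicate 1 kept X-II replicate 1, where ribosomal genes were lower by a median of −0.49. In replicates 2 to 4 alone the ribosomal call was kept. Genes of the intracellular pathogen response had a median of 0.55 (camera adjusted p = 5.51e-04; adjusted p = 0.697 with an estimated correlation), with 3 higher adjusted over the list alone. In replicate 1 of N2, X-V and X-II, neuronal genes were lower by medians of −1.46, −1.30 and −1.33, and histone genes higher by 1.03, 1.22 and 0.49.

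Molting-cycle genes were lower as a group in X-II as well, with a median of −0.26 (camera adjusted p = 5.51e-04; adjusted p = 0.791 with an estimated correlation) and 1 of 69 lower adjusted over the list alone. Under the block 3 of them fell, among them mlt-10 (−1.43 ± 0.26) and the fibrillin homolog fbn-1 (−1.36 ± 0.24), and 1 rose. As mlt-10 lies in the II left window, its fall is not separate from that of the window. Heat shock and unfolded protein response genes had a median of −0.29 (camera adjusted p = 0.00749; adjusted p = 0.791 with an estimated correlation), and genes of the epidermis and seam −0.38 (camera adjusted p = 0.0335; adjusted p = 0.791 with an estimated correlation). Adjusted over the list alone, 0 members of either passed edgeR. The molting call was lost without N2 replicate 4 or X-II replicate 1 (adjusted p = 0.0924 and 0.0752). The heat shock call was lost without N2 replicate 2, X-II replicate 1 or X-II replicate 3 (adjusted p from 0.0983 to 0.226), and in replicates 2 to 4 alone (adjusted p = 0.0918). The epidermal call was lost without N2 replicate 2, 3 or 4, or X-II replicate 1 or 4 (adjusted p from 0.0535 to 0.174). In replicates 2 to 4 alone the molting and epidermal calls were kept. With the block, 3 more lists passed camera, all lower: vitellogenins (−1.38, adjusted p = 0.0305), germline (−0.16, adjusted p = 0.0401) and histone methyltransferases and demethylases (−0.11, adjusted p = 0.0432). With the block and an estimated correlation these 3 did not pass (adjusted p = 0.556, 0.726 and 0.556). The share of vitellogenins in replicate 1 differed between strains, as given above. That of the germline list was 3.20%, 2.66% and 1.17% in N2, X-V and X-II. For histone methyltransferases and demethylases it was 0.167%, 0.170% and 0.154%. Molting genes were lower in replicate 1 by medians of −0.85, −0.48 and −0.58 in N2, X-V and X-II.

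The fusion strains also differed from each other by a direct test, in which N2 enters only through the filter, the scaling and the shared estimate of spread. The V right window was lower in X-V than in X-II, with a median log2 difference of −0.66 and 89 of 100 genes below 0 (camera adjusted p = 3.92e-18; adjusted p = 0.00669 with an estimated correlation). The II left window was higher in X-V by 0.47 (camera adjusted p = 3.28e-23; adjusted p = 0.00115 with an estimated correlation). The relative log2 CPM of the V right window was lower in X-V in 4 of 4 pairs (exact permutation p = 0.0286), and that of the II left window higher in 4 of 4 pairs (exact permutation p = 0.0286). Over 13 regions the adjusted p was 0.186 for both, and without the 7 leftmost genes the II left window gave an exact permutation p of 0.0857. One gene of the V right window was called lower, mnr-1 (−1.27 ± 0.22, SE; 11.5 ± 0.323 against 27.7 ± 4.00 CPM), named after its value was seen.

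By edgeR, 24 genes differed between X-V and X-II, 8 higher and 16 lower in X-V, and 17 of them were also called in X-II against N2. The higher ones with the largest differences were gmeb-1 (9.02 ± 0.72, SE), sqt-2 (8.48 ± 0.88), best-4 and best-3 (7.76 ± 1.01); best-4 had 198 counts in X-V and 0 in X-II. Among the lower ones with a gene name, the largest differences were those of bgnt-1.2 (−4.98 ± 0.66), bgnt-1.3 (−4.72 ± 0.56), cnc-6 (−4.65 ± 0.79) and cnc-2 (−4.57 ± 0.66). Called genes with only a sequence name reached −5.55. With each of the 8 libraries left out in turn, gmeb-1 and sqt-2 passed in all 8 fits, bgnt-1.3 in 4, best-3, best-4 and bgnt-1.2 in 2, cnc-2 in 1 and cnc-6 in 0. The caenacin cnc-4 did not pass in this comparison (−2.20 ± 0.46, adjusted p = 0.117). For the 8 genes named above as higher or lower, the edgeR adjusted p ranged from 4.83e-04 to 0.0446. DESeq2 called 202 genes and the block 241, 66 higher and 175 lower, while a fit of the 2 groups alone called 8; leaving out 1 library gave 3 genes without X-V replicate 2, 5 without X-V replicate 3, 4 without X-V replicate 4 and 4 without X-II replicate 3. The count was 14 without X-V replicate 1, 10 without X-II replicate 2 and 7 without X-II replicate 4. None of the 10 genes of the dosage compensation complex was called.

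Fold changes of X-V and X-II against N2 were correlated across the 13186 genes, which are not independent replicates (Pearson r = 0.476). Both comparisons use the same N2 libraries, and 20 simulations of unchanged groups gave r = 0.494 ± 0.0124 (SD). The covariance was 0.147 against a simulated 0.0797. With N2 split into 2 and 2 libraries, r was −0.29 on average over 6 splits, and 0.14 with the replicate block. Every such split leaves N2 replicate 1, with its adult and germline transcripts, on 1 side only. Without the block this pushes the 2 sets of fold changes in opposite directions, so the negative r does not show opposite changes in the 2 strains. Under the block srw-85 and herc-1 were called lower in both strains, and 0 genes were called higher in both. Simulated unchanged groups shared 0 lower calls and on average 0.05 higher calls, and independent lists of these sizes share 0.033 and 0.246. The simulation leaves out real changes and the independent lists leave out the shared N2 libraries, so a high N2 level alone could place a gene in both. The simulation also used the spread of the blocked fit, the same replicate effects in each strain and genes drawn independently. Its SD and its covariance therefore do not cover replicate effects that differ between strains, and the higher observed covariance does not show shared changes.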

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

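All tests of explanations in this part were chosen after the results were seen. Values of 4 libraries per strain were searched for a library far from the other 3, and 14 of 58 groups held one. The limit used flags about 1 in 20 groups of independent, normally distributed values. Many of the values searched were raw CPM or shares of counts, and several measures share the replicate 1 difference. The 14 of 58 therefore cannot be set against that rate. Vitellogenins stood apart in replicate 1 of every strain (12.2% in N2, 12.58% in X-V, 6.81% in X-II), as did the germline list (3.20%, 2.66% and 1.17%). The mean log2 CPM of the II left window relative to other autosomal genes stood apart in replicate 1 of N2 (−0.40) and of X-V (−0.50), and that of X in replicate 1 of N2 (−0.71) and of X-V (−0.68). Single genes with a library apart were suex-1 (53.5 CPM in X-II replicate 4), gtnt-25 (0.955 CPM in N2 replicate 4), best-4 (1.22 CPM in N2 replicate 1) and osta-1 (0.112 CPM in X-II replicate 3). The osta-1 value is 1 read against 0 in the other 3 X-II libraries, so nothing rests on it. The fusion strains also differed from each other by a direct test, in the V right window (−0.66), in the II left window (0.47) and in 24 genes.

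Older animals in the replicate 1 collections would raise germline genes in all 3 strains, and the lowest of the 3 medians was 4.00 on the log2 scale. This restates the pattern and cannot test its source. A share of counts going to vitellogenins would lower other genes, by at most 0.19 on the log2 scale, so the lowest median without them before scaling, 4.01, was fixed beforehand and tests nothing. Replicate 1 had the lowest total count in 1 of 3 strains, so lower depth does not account for the pattern. Adult animals among the larvae could be the source, which stays open, as no record of the collections was available.

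The loss of 1 of 2 copies of the whole V right window in X-V would give a log2 difference near −1. The mean over 4 pairs was −0.52 ± 0.15 (SD). The loss of 1 copy of a part of the window was not tested. With scaling on autosomal genes outside the windows the median was −0.56. Scaling factors move all genes of a library alike, so this check could not remove a difference between the window and other genes. An influence that weakens with distance from the end would leave a rise among the genes of the window (Spearman rho 0.348, permutation p = 4.60e-04, other 11 ends −0.174 to 0.198) and over the 10 bins outside it (rho 0.770, permutation p = 0.0124, other 11 ends −0.564 to 0.0424), and both rose. The permutations, here and for II, shuffled genes or bins within 1 profile and ignored neighbours that vary together and the spread between libraries. The other ends were compared once the V right trend had been seen, and the p values are not adjusted over ends. In X-II against N2 the outer bins of 4 ends outside the fusion had a permutation p under 0.05, all falling (lowest rho −0.867). Dosage compensation reaching from X into V could act in this way if the V right end is the joined one, which the labels do not say; the rho of 0.770 does not tell it from other effects, and binding of the complex was not analysed here.

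A deletion of the 7 leftmost genes of II in both copies would account for the counts of X-II, in which none of them kept more than 2.41% of its N2 level; DNA reads were not used here. For the other 93 genes of the window, the loss of 1 of 2 copies of them all does not account for the difference. Its mean over pairs was −0.43 ± 0.20 (SD). The loss of 1 copy of a part of the window, such as the genes next to the 7, was not tested. The difference shrank with distance, with medians of −0.70, −0.23, −0.13 and 0.10 over successive bins of 50 genes, the first of which holds the 7 genes. Among the 93 genes rho was 0.242 (permutation p = 0.0201), but the V left end, which is not part of this fusion, reached 0.246, and neither the 10 outer bins (rho 0.0303, permutation p = 0.947) nor all 12 (rho 0.441, permutation p = 0.154) passed, so a graded influence stays open. Dosage compensation reaching into II could lower genes of the window, and the rho of 0.242 leaves it undecided.

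Each result was also set against the 35 splits of the same 8 libraries into 4 and 4, the real one included, with camera results as −log10 p. Only the real split gave a result as large for the V right window in X-V against N2 (32.6, highest other 22.9), the II left window in X-II against N2 (19.2, highest other 12.8), and in X-V against X-II the V right window (18.2, highest other 10.2) and the II left window (23.6, highest other 16.3). The same holds for the 29 genes of X-II against N2 and the 24 of X-V against X-II (highest other 0 in both), so for each of these 1 of 35 splits was as large. The pairing by replicate number rests largely on replicate 1. If it holds, only 8 of the 35 splits part all 4 pairs as the real one does. The real split was the highest of these 8 for each of the 6 results, but 8 are too few for a share under 0.05. With the replicate block, 2 of 35 splits were as large for the II left window in X-II against N2 (24.2, highest other 24.9), and the highest other parts 2 of the 4 pairs. With the block, a split that parts 0 pairs called 229 genes in X-V against N2, against 9 in the real one. Such a split is estimated only through the libraries of the third strain, and whether the 229 reflect a structure of the samples was not tested. Results as large came from 26 of 35 splits for the V left end in X-V (0.376, highest other 1.595), 26 for the II right end in X-II (0.100, highest other 2.39), 20 for X in X-V (0.356, highest other 5.50) and 20 for X in X-II (1.02, highest other 7.67). For the 3 lists called in X-V against N2 they came from 34 (highest other 17), for the 9 in X-II against N2 from 23 (highest other 16) and for the 8 in X-V against X-II from 26 (highest other 17), so chance is not excluded for the list calls. Among the 8 splits that part all 4 pairs, results as large came from 5 for the V left end in X-V and 7 for the II right end in X-II. They came from 2 for X in X-V (highest other 0.491) and 3 for X in X-II (highest other 1.88). For the lists of the 3 comparisons they came from 8, 2 and 5. The counts of 0 genes in X-V against N2 and of 0 other chromosome ends in both comparisons with N2 are reached by all 35 splits by construction, so this comparison says nothing about them.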

How the results depend on the processing

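Tests with replicates 2 to 4 alone, with the block joined to an estimated correlation, and of the other ends were chosen after the results were seen; the cause of the changes given here was not tested. The V right window in X-V kept its direction and call in all 12 alternatives (−0.63 to −0.47) and without each library (−0.63 to −0.49). The II left window in X-II kept both in 12 of 13 and without each library (−0.76 to −0.44); with the block and an estimated correlation it was −0.45 and no longer passed (adjusted p = 0.0587). Genes changed in X-V against N2 were 18 by DESeq2, 9 with the block, 2 in replicates 2 to 4, 1 there with the block, and 0 to 1 without single libraries. For X-II against N2 they were 382, 686, 134 and 160, with 16 after upper quartile scaling, 16 without a filter, 6 in the 2 groups alone, and 4 to 27 without single libraries. For X-V against X-II they were 202, 241, 74 and 69, with 8 in the 2 groups alone, 15 by glmTreat, and 3 to 18 without single libraries. The V left end in X-V was −0.00115 without a filter and −0.0152 over 50 genes; after RLE scaling the II right end in X-II was −0.0321 and X in X-V was −0.00320. Without single libraries the II right end was −0.0751 to 0.160, X in X-V −0.0502 to 0.118 and X in X-II −0.0163 to 0.174. Other ends past the threshold were 2 over windows of 200 genes, 1 in replicates 2 to 4 with the block, and 0 to 2 without single libraries. Lists past the threshold in the comparisons with N2 were 12, but 0 with an estimated correlation, 0 with that and the block, and 10 to 20 without single libraries. Ribosomal proteins in X-V against N2 changed direction in the test without N2 replicate 1, with a median of 0.0277, and reached 0.39 without X-V replicate 1. Each of these fits kept replicate 1 of the other strain compared, and in replicates 2 to 4 alone the call was kept. The correlation of the fold changes turned to −0.29 with N2 split, and was 0.14 with the block as well. As N2 replicate 1 falls on 1 side of every split, the negative value does not show opposite changes. In X-V against X-II the block added vitellogenins to the lists past the threshold (1.597, camera adjusted p = 0.00724, and 0.642 with an estimated correlation). By fry the intestine list passed with the block only (adjusted p = 0.0305, 0.464 without). Apart from these and the counts, genes and lists given with the results, it changed no other call of a region or list. Runs of genes without reads held 12 genes, and 8 to 17 under other limits. The spread between libraries limits what single genes show. Of 100 simulated 4-fold changes in X-V against N2, 11 were found without the block and 85 with it, at the same depth. These counts were drawn with the replicate effects and spread of the blocked fit, so the gain with the block was built in.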

Other observations

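Hypotheses and tests in this part were chosen after the results were seen. A second group of genes with few reads in X-II lies inside chromosome V: C13A2.9 had 2 counts over the 4 X-II libraries against 148 in N2, gtnt-6 0 against 65, C13A2.4 1 against 70, gtnt-20 2 against 47, and F07G11.1 5 against 160. These 5 genes were also low in X-V, with 22, 12, 5, 10 and 25 counts. Several belong to a family of similar genes.

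Further stress and metabolic genes differed between X-II and N2 under the replicate block and not without it, and were named after their values were seen. The antimicrobial-type peptide nlp-34 was higher by 4.14 on the log2 scale (edgeR adjusted p = 3.52e-04), and the acyl-CoA synthetase acs-2 by 2.35. The gene dod-3 was higher by 2.22 and dod-24 lower, with a log2 fold change of −3.22. DESeq2 also called nlp-34 and dod-24, as did edgeR in replicates 2 to 4, and dod-24 passed edgeR without N2 replicate 1 (adjusted p = 0.0414). In replicates 2 to 4 with the block, dod-3 passed as well.

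Lists that did not pass camera in X-V against N2 had these median log2 fold changes: dosage compensation −0.08, ChIP target proteins −0.10, sex determination −0.12, histone methyltransferases and demethylases −0.06, telomere maintenance 0.01, cuticle collagens −0.17, heterochronic pathway −0.22, germline −0.08, spermatogenesis −0.07, vitellogenins −0.53, histones 0.19, innate immune effectors 0.07, intracellular pathogen response 0.03, heat shock 0.06, detoxification 0.10, fatty acid metabolism −0.07, insulin and stress resistance 0.21, muscle −0.05, intestine −0.07, epidermis −0.08, and the F-box and MATH families 0.02. The 2 tested embryonic regulators had a median of 0.08. In all of them 0 members were called, by edgeR, and 0 adjusted over the list alone (adjusted p = 0.984 with an estimated correlation for each tested list). Mitochondrially encoded genes were absent from the files. The test pointed down for telomere maintenance and innate immune effectors, and up for spermatogenesis, against the sign of their medians. With the replicate block the vitellogenin median turned to 0.31, and that of cuticle collagens was −0.06.

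In X-II against N2 the lists that did not pass had medians of −0.17 for dosage compensation, −0.20 for ChIP target proteins, −0.37 for sex determination, −0.16 for histone methyltransferases and demethylases, −0.17 for telomere maintenance, 0.22 for cuticle collagens, −0.47 for the heterochronic pathway, −0.72 for the germline, 0.75 for spermatogenesis, −1.70 for vitellogenins, 0.08 for detoxification, 0.24 for fatty acid metabolism, 0.06 for muscle, 0.18 for intestine, and 0.15 for the F-box and MATH families. The 2 embryonic regulators had a median of −0.96. Adjusted over the list alone, 9 detoxification genes rose and 3 fell, 2 genes of fatty acid metabolism rose and 3 fell, and 2 intestinal genes rose (adjusted p = 0.921, 0.921 and 0.830 with an estimated correlation). The test pointed down for muscle and for the F-box and MATH families, against the sign of their medians. With the replicate block the embryonic regulators had a median of 0.006, and sex determination −0.12.

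Between X-V and X-II, 8 lists passed camera. Lower in X-V were ribosomal proteins (−0.23), histones (−0.38), innate immune effectors (−0.36), the intracellular pathogen response (−0.52), insulin and stress resistance (−0.74), intestine (−0.44) and neurons (−0.36), and heat shock was higher (0.21). With an estimated correlation 0 of them passed, the lowest adjusted p being 0.0622 for insulin and stress resistance. With the block vitellogenins passed as well (1.597, adjusted p = 0.00724), but not with the block and an estimated correlation (adjusted p = 0.642). Among chromosome ends, the median and the test differed in sign for the I left end (0.01), the I right end (−0.02) and the III right end (0.01) in X-V against N2, and for the I right end (−0.03) in X-II against N2.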
